A study of Mus musculus with 18 samples.

How the data were processed

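The series holds 18 Affymetrix mouse arrays of RNA from blood platelets and from Th1 and Th2 CD4+ T cells of BALB/c mice, taken 0, 24 and 48 h after cecal ligation and puncture. This operation lets gut bacteria into the abdomen and is a model of sepsis with lung injury. Per the labels, the cells were isolated from exsanguinated blood by negative selection, and the RNA was amplified and pooled over several mice. Replicates are named here by a number in the array titles whose meaning the labels do not give. The deposited values are linear signal intensity values of 45101 probe sets on each array. Their mean without the lowest and highest 2% of probe sets was 150 on all 18 arrays, and the array medians ran from 38.2 to 95.0. The titles, per the labels, begin with the name of a method that returns log2 values of equal distribution, which these values were not. The software that made them is not given in the sources used here.

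A choice made before the data were examined applied to linear values: log2 was taken and the 18 arrays were quantile normalised together. The probe table gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160, and 64 further probe sets were Affymetrix controls. Gene IDs matched 34754 of those with 1 symbol to the reference of mouse genes, and 0 symbols changed. Each of the 18193 genes with a symbol was represented by its probe set of highest mean. A gene was tested if it exceeded the median of its array on at least 2 arrays, which left 17363 genes. Precision is limited by the number of arrays.

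The 9 groups of cell type and time were fitted as 1 factor in limma 3.58.1 (R 4.3.3) with a spread that depends on intensity, 9 residual degrees of freedom and a median of 12.7 prior degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the genes tested. The 13 comparisons chosen before the data were examined were platelets against T cells, Th1 against Th2, the means over cell types of 24 h against 0 h, 48 h against 0 h and 48 h against 24 h, each cell type at 24 and 48 h against 0 h, and the differences of the 48 h response between platelets and T cells and between Th1 and Th2. A further 3 comparisons were chosen after seeing the data: platelets against Th1, platelets against Th2, and the difference of the 24 h response between Th1 and Th2. Means over cell types weighted the groups equally.

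Members of 31 fixed gene lists, 749 in all, were looked up among the genes tested, and 89 were not matched. A list was tested against all other genes with camera (preset correlation 0.01) where at least 5 members were measured, adjusted over the 403 tests of the 13 comparisons and separately over those of the 3 added comparisons. The same tests were run with an estimated correlation and with fry, which tests whether the genes of a list move 1 way on balance. The rule for named genes, set before the data were examined, gave the 5 largest changes in each direction past the threshold without overlap between the compared arrays, up to 4 members of each list past the threshold or else 2 of its brightest, and genes fixed beforehand. The text names all of the first kind and a part of the others, and that part was chosen after the values were seen. The condition on overlap was not applied to differences of responses. The bounds for changes from dim signals were added after the values were seen. Gene models without a proper symbol were passed over.

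Array quality was described by the 9 hybridization control probe sets, by the 3' minus 5' differences of the actin and Gapdh controls, and by rank correlations between arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Each comparison was tested on simulated data of 17363 genes. Of genes changed by 4 on the log2 scale, 95.5% were recovered for platelets against T cells, 88.1% for Th1 against Th2, 62.7% for 24 h against 0 h, 83.6% for 48 h against 0 h and 83.6% for 48 h against 24 h. Within platelets the share was 34.3% at 24 h and 25.4% at 48 h, within Th1 9% and 40.3%, and within Th2 4.5% and 14.9%. For the differences of responses it was 10.4% for platelets minus T cells at 48 h, 1.5% for Th1 minus Th2 at 48 h and 0% for Th1 minus Th2 at 24 h. The added comparisons of platelets with Th1 and with Th2 recovered 80.6% and 83.6%. Most genes changed by 2 were missed. The share recovered at that size was 35.8% for platelets against T cells, 10.4% for Th1 against Th2 and 14.9% for 24 h against 0 h. Within any cell type it was at most 4.5%. In 20 simulations of 24 h against 0 h without an effect, camera called 0 lists, and it called the neutrophil list when that list was moved. The simulated noise was independent between genes, so these runs do not show how camera behaves on correlated genes.

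Alternatives were no filter, every probe set, values as deposited, centring on the median, the replicate number as a block, array weights, a spread without a trend, fits within 1 cell type and leaving out each array. Settings chosen after seeing the data were a fit without the 4 arrays of highest hybridization control signal and a fit with that signal as a covariate. Probe sets with several symbols or none stayed out of the gene-level tests. Hbb-b1 was not analysed here, since no probe set carried that symbol alone. Hbb-b2, Ighm and Ighv14-2 belong to gene families whose members share sequence, so their values are uncertain. Named genes with several probe sets made 267 pairs of gene and comparison. In 74 of these a further probe set had the opposite sign, and in 1 it was past the threshold (Runx3, platelets against Th2).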

Results

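Gene expression was measured on 18 arrays of blood cell RNA from mice with cecal ligation and puncture, to map how platelets and T helper cells might act on each other over time. Platelets had 2 arrays at each of 0, 24 and 48 h. Th1 cells, the interferon-producing T helper cells, had 2 arrays at 0 h, 1 at 24 h and 3 at 48 h. Th2 cells, which make interleukin 4, had 1 array at 0 h, 2 at 24 h and 3 at 48 h. Time 0 was the time of the operation. The arrays are of pooled, amplified RNA and their replicates may be technical, so the p-values measure only the spread between these arrays. The lone arrays of Th1 at 24 h and Th2 at 0 h were assumed to vary like the others. Detection calls were not used here, and many genes had a group mean under the median of all probe sets, 5.97 on the log2 scale. For these, if past the threshold, a bound (at least or at most) gives the difference with such means raised to that median. Differences of responses carry no such bound.

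The array controls differed between times. The hybridization controls, added in fixed amounts, averaged 14.96 ± 0.96 (log2, SD, n = 5) at 0 h, 14.64 ± 1.30 (n = 5) at 24 h and 12.80 ± 1.66 (n = 8) at 48 h. The control level on platelet, Th1 and Th2 arrays was 14.07 ± 1.81, 13.77 ± 1.53 and 13.88 ± 1.98 (n = 6 each). Platelets 0 h replicate 1 had a control level of 16.10 and a median rank correlation of 0.193 with the other arrays, which lay between 0.436 and 0.674. Pairs of arrays of 1 group had a median correlation of 0.656 (n = 11 pairs, 0.323 to 0.842), and pairs from different groups 0.592 (n = 142, 0.188 to 0.842). The median SD of a gene within a group was 1.31 for platelets at 0 h, 0.856 at 24 h and 0.416 at 48 h.

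**Figure D1:**
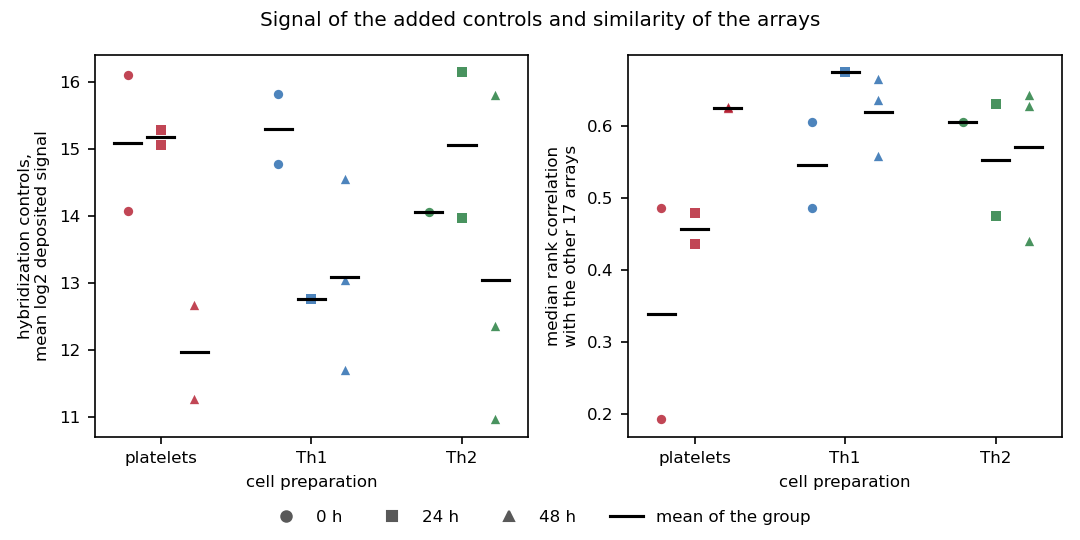
Mean log2 signal of the hybridization controls and median rank correlation with the other arrays, by cell preparation, with a point per array, marker shapes for 0, 24 and 48 h and lines for group means. Control levels ran from 10.97 to 16.14, and platelets 0 h replicate 1 had the lowest correlation, 0.193.

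Marker genes showed what each preparation held. Pf4, the platelet chemokine, had a log2 signal of 15.69 ± 0.39 (SD, n = 6) on platelet arrays, 16.06 ± 0.26 on arrays labelled Th1 and 11.40 ± 1.61 on arrays labelled Th2. Cd3e, a chain of the T cell receptor complex, was at 6.14 on platelet, 9.16 on Th1 and 8.80 on Th2 arrays. The B cell surface gene Ms4a1 was at 8.63, 8.82 and 12.75, and Alas2, a heme synthesis gene of red cell precursors, at 13.60, 3.45 and 9.54. The mean of the platelet and megakaryocyte list was 10.92 ± 0.95, 12.22 ± 0.38 and 7.33 ± 0.82 on the same arrays, and that of the T cell list 6.21 ± 0.59, 8.43 ± 0.48 and 8.42 ± 0.91. Neutrophil genes averaged 9.23, 6.53 and 7.38, and monocyte and macrophage genes 9.44, 7.65 and 7.22.

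**Figure D2:**
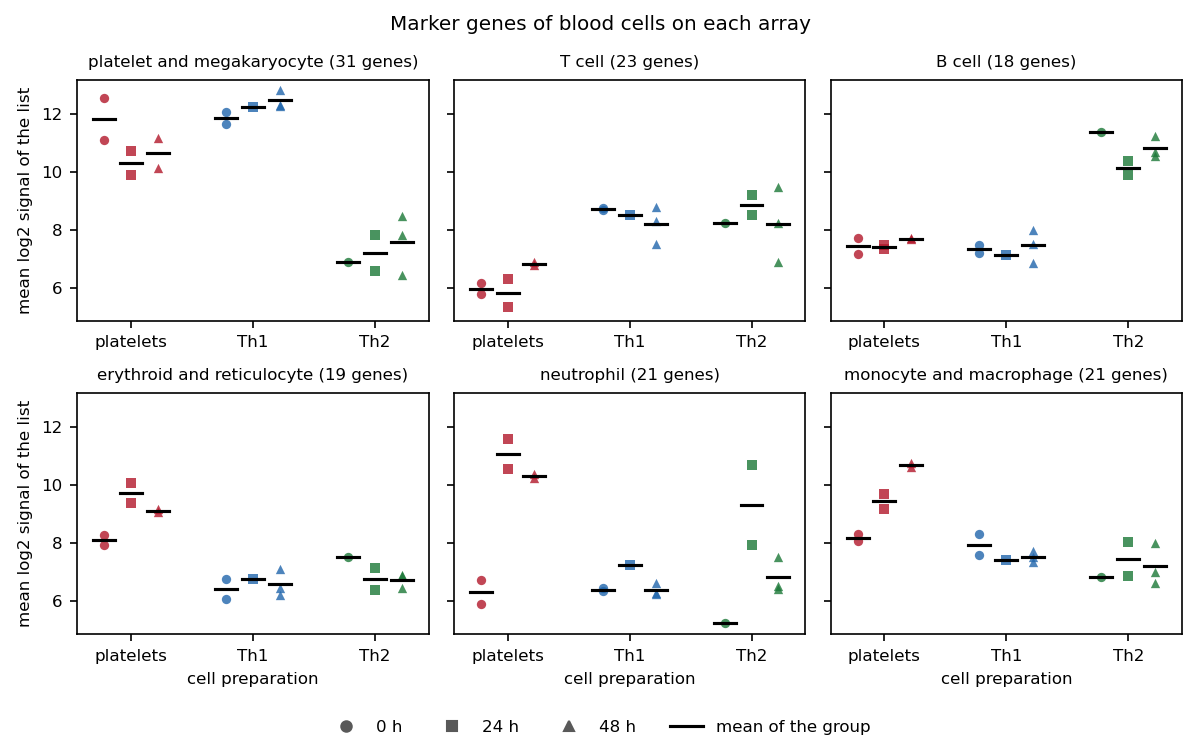
Mean log2 signal of marker lists of blood cells on each array, by cell preparation, with a point per array, marker shapes for 0, 24 and 48 h and lines for group means. The platelet list averaged 12.22 on Th1 arrays against 7.33 on Th2 arrays, and the B cell list 7.36 against 10.68.

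Platelet arrays carried some red cell and myeloid transcripts above the T cell arrays, with the 3 times averaged. At 0 h alone the neutrophil list averaged 6.31 on platelet, 6.40 on Th1 and 5.24 on Th2 arrays, and the monocyte and macrophage list 8.18, 7.94 and 6.83. Alas2 was higher by 6.72 ± 0.59 (at least 5.55, log2 difference, SE; 6 platelet against 12 T cell arrays; limma adjusted p = 4.86e-07), and Slc25a37, which brings iron into mitochondria, by 4.85 ± 0.56 (at least 4.77, 1.76e-05). S100a8, a neutrophil alarmin subunit, was higher by 3.86 ± 0.50 (5.35e-05), and Csf1r, the receptor that maintains monocytes, by 3.76 ± 0.55 (0.000211). Pf4 and Ppbp, chemokines of platelet granules, were higher by 2.11 ± 0.41 (0.00233) and 2.16 ± 0.42 (0.00246), with the Th1 and Th2 arrays averaged. Il7r, the interleukin 7 receptor of resting T cells, differed by -4.17 ± 0.51 (3.03e-05), and Cd3e by -2.85 ± 0.55 (at most -2.55, 0.00222). Also among the most different were Apol11b (4.85 ± 0.69, at least 3.67), Fam220a (4.62 ± 0.45), Rec114 (4.20 ± 0.69, at least 2.84) and the fatty acid carrier Fabp4 (4.15 ± 0.59, at least 3.19). Lower in platelets were Jakmip1 (-5.04 ± 0.39, at most -4.38), the splicing factor Hnrnpa1 (-4.70 ± 0.39, at most -4.15), Dnah8 (-3.85 ± 0.51, at most -2.73) and the calcium channel Itpr3 (-3.82 ± 0.61, at most -1.78). For Csf1r 2 of 3 probe sets passed (1.38 to 3.76). Of the others, 1 of 4 passed for Fabp4 (0.19 to 4.15) and for Jakmip1 (-5.04 to -0.22), 2 of 3 for Hnrnpa1 (-4.70 to -1.47), and 1 of 2 each for Rec114 (1.47 to 4.20) and Dnah8 (-3.85 to -1.86). Of 17363 genes, 1337 passed the threshold, 398 higher and 939 lower in platelets; the median difference of all genes was -0.039, against 0.163 in the values as deposited. Of 19 erythroid and reticulocyte genes, 8 were higher, 0 lower and 11 not past (9 higher adjusted over the list alone; camera adjusted p = 1.35e-11, adjusted p = 0.0148 with an estimated correlation). Of 21 monocyte and macrophage genes, 14 were higher and 7 not past (16 adjusted over the list alone; 1.51e-14, adjusted p = 0.0493 with an estimated correlation), and of 21 neutrophil genes 16 were higher and 5 not past (16 adjusted over the list alone; 3.9e-15, adjusted p = 0.0887 with an estimated correlation). Among 31 platelet and megakaryocyte genes, 10 were higher and 21 not past (18 adjusted over the list alone; 1.23e-12, adjusted p = 0.214 with an estimated correlation). In the T cell list of 23 genes, 14 were lower and 9 not past (17 adjusted over the list alone; 3.71e-14, adjusted p = 0.113 with an estimated correlation). Cytosolic ribosomal proteins were lower in 27 of 43 genes with 16 not past (33 adjusted over the list alone; 5.06e-17, adjusted p = 0.113 with an estimated correlation). The count was 2968 without platelets 0 h replicate 2, 688 without platelets 48 h replicate 1, 703 without platelets 48 h replicate 4 and 812 with a spread that did not depend on intensity.

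Arrays labelled Th1 and Th2 differed in platelet and B cell transcripts, and their defining T cell genes were not past the threshold. Slc6a4, the serotonin transporter of platelets, was higher on Th1 arrays by 7.49 ± 0.53 (at least 5.13, log2, SE; 6 against 6 arrays; adjusted p = 2.77e-08), and Gp9, part of the von Willebrand factor receptor, by 7.35 ± 0.76 (at least 6.50, 7.91e-07). Ebf1, a transcription factor of B cells, was lower by a difference of -5.47 ± 0.70 (at most -4.60, 1.22e-05), and Cd74, the chaperone of MHC class II, of -4.05 ± 0.56 (4.17e-05). The B cell gene Cd79a was not past the threshold (-0.79 ± 0.63, limma adjusted p = 0.709). Also higher were Mfsd2b (7.34 ± 0.86, at least 5.15), Myl9 (7.17 ± 0.76, at least 6.70) and Sh3bgrl2 (6.95 ± 0.93, at least 6.56). Lower were Ighv14-2 (-5.95 ± 0.70, at most -4.92) and Srpk3 (-5.81 ± 0.92). Hbb-b2 and Alas2 differed by -7.06 ± 0.89 (at most -5.44, 1.06e-05) and -6.49 ± 0.72 (at most -4.15, 2e-06). Gzma, a cytotoxic granule protease, was higher on Th1 arrays by 3.55 ± 0.73 (0.00386), and Eomes, a regulator of cytotoxic cells, by 3.15 ± 0.67 (at least 2.23, 0.00506). Tbx21, the Th1 regulator, differed by 1.01 ± 0.56 (0.504) and Ifng, the Th1 cytokine, by 2.105 ± 0.987 (0.367). Gata3, the Th2 regulator, differed by 1.01 ± 1.01 (0.787) and Il4 by 0.21 ± 1.07 (0.974). In the simulation of this comparison, 10.4% of genes changed by 2 were recovered, so differences of that size could be missed. Cd4 differed by -2.15 ± 0.88 (0.26), Cd8a by -0.56 ± 0.73 (0.856) and Foxp3, the regulator of regulatory T cells, by -0.10 ± 0.91 (0.989). Gata3 and Il4 had 4 of 6 group means under the median of all probe sets. Of the probe sets of Ebf1, 3 of 5 passed (-5.47 to 0.26), and 2 of 3 for Srpk3 (-5.81 to -0.88). It was 1 of 2 for Hbb-b2 (-7.06 to -2.44), Mfsd2b (1.80 to 7.34) and Eomes (2.94 to 3.15). In all, 674 genes passed, 481 higher and 193 lower on Th1 arrays. Of 31 platelet and megakaryocyte genes, 29 were higher and 2 not past (29 adjusted over the list alone; camera adjusted p = 1.33e-71, adjusted p = 0.0204 with an estimated correlation). In the B cell list, 14 of 18 genes were lower and 4 not past (15 adjusted over the list alone; 3.74e-30, adjusted p = 0.00615 with an estimated correlation), and in the MHC class II list 9 of 10 were lower and 1 not past (9 adjusted over the list alone; 3.9e-18, adjusted p = 0.0148 with an estimated correlation). Coagulation and fibrinolysis genes were higher in 6 of 18, with 12 not past (9 adjusted over the list alone; 2.9e-07, adjusted p = 0.0368 with an estimated correlation). None of the 16 Th1 genes (camera adjusted p = 0.545) and none of the 14 Th2 genes (0.88) passed in limma, over all genes or adjusted over the list alone. The count was 1184 without platelets 0 h replicate 1 and 1165 without platelets 0 h replicate 2, which enter this comparison through the spread alone.

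Platelet arrays were also set against each T cell preparation separately, a comparison chosen after seeing the data. Against Th1, Alas2 was higher in platelets by 9.97 ± 0.69 (at least 7.63, log2, SE; 6 against 6 arrays; adjusted p = 2.18e-08) and S100a8 by 5.16 ± 0.58 (1.47e-05), whereas Pf4 differed by -0.38 ± 0.48 (0.764) and Itga2b, the platelet fibrinogen receptor subunit, by -2.27 ± 0.48 (0.0146). Hbb-b2 (9.74 ± 0.85, at least 8.12), Slc4a1 (8.19 ± 0.73, at least 7.66), Fech (6.49 ± 0.51) and Bpgm (6.38 ± 0.55), genes of red cells, were higher too. Lower were Jakmip1 (-4.23 ± 0.46, at most -3.57), Cd6 (-4.02 ± 0.75, at most -2.35), Mcpt8 (-3.97 ± 0.73, at most -2.13), Il7r (-3.94 ± 0.60) and Satb1 (-3.73 ± 0.73, at most -3.26). Of the probe sets of Jakmip1, 1 of 4 passed (-4.23 to 0.48), of Slc4a1 2 of 3 (1.03 to 8.19), of Fech 3 of 4 (-0.20 to 6.49) and of Satb1 3 of 5 (-3.88 to -0.17). The T cell genes Cd3d and Cd3e differed by -3.76 ± 0.63 (at most -2.80, 0.0023) and -2.97 ± 0.64 (at most -2.67, 0.0166). Here 291 genes passed, 146 higher and 145 lower in platelets, with a median difference of all genes of -0.139, against 0.084 in the values as deposited. Of 31 platelet genes, 3 were lower and 28 not past (11 lower adjusted over the list alone; camera adjusted p = 2.51e-09, adjusted p = 0.34 with an estimated correlation). Against Th2, Pf4 was higher in platelets by 4.59 ± 0.48 (1.54e-06) and Cd79b, part of the B cell receptor, differed by -5.08 ± 0.48 (6.26e-07). The largest differences were those of Mmd (5.98 ± 0.84), Slc6a4 (5.80 ± 0.51, at least 3.44), Gp9 (5.74 ± 0.73, at least 4.90), Cavin2 (5.74 ± 0.67, at least 5.01) and Angpt1 (5.68 ± 0.67, at least 2.82). On the other side were Srpk3 (-6.11 ± 0.87), Cd40 (-6.02 ± 0.60, at most -5.59), Jakmip1 (-5.84 ± 0.46, at most -5.18), Hnrnpa1 (-5.75 ± 0.45, at most -5.20) and Fbxw2 (-5.57 ± 0.81, at most -4.78). For Angpt1 1 of 2 probe sets passed (-0.08 to 5.68), and for Fbxw2 1 of 6 (-5.57 to 0.73). For Jakmip1 it was 1 of 4 (-5.84 to -0.41), and 2 of 3 for Mmd, Srpk3 and Hnrnpa1. Of 17363 genes, 1913 passed, 716 higher and 1197 lower, with a median difference of all genes of 0.029, against 0.174 in the values as deposited. Of 31 platelet genes, 28 were higher and 3 not past (28 adjusted over the list alone; 2.85e-38, adjusted p = 0.0411 with an estimated correlation). Against Th1 the count was 533 and 2109 without platelets 0 h replicates 1 and 2, 144 and 125 without platelets 48 h replicates 1 and 4, 159 and 180 without Th1 0 h replicates 1 and 2, 193 and 179 without Th1 48 h replicates 1 and 4, and 93 with a spread that did not depend on intensity. Against Th2 it was 3133 without platelets 0 h replicate 2 and 1248 without platelets 48 h replicate 1.

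At 24 h against 0 h, averaged over the 3 cell types, some neutrophil, interferon, cytotoxic and cell cycle genes rose. Lcn2, an iron-binding granule protein of neutrophils, rose by 8.46 ± 0.93 (at least 5.12, log2, SE; 5 against 5 arrays; adjusted p = 5.78e-05). S100a9, the partner of S100a8, rose by 6.76 ± 0.94 (at least 5.61, 0.00108), Chil3, a chitinase-like protein of myeloid cells, by at least 4.20 (0.00308), and S100a8 by 5.69 ± 0.64 (5.78e-05). Saa3, an acute phase protein, rose by 6.21 ± 0.76 (at least 4.65, 0.000211), and Slfn4, an interferon-inducible gene of myeloid cells, by 6.79 ± 0.75 (at least 5.78, 5.78e-05). Ifit1, an antiviral interferon target, rose by 4.53 ± 0.76 (at least 4.34, 0.00632), and Gbp2, a guanylate-binding protein induced by interferon gamma, by 3.90 ± 0.55 (at least 3.74, 0.00117). Gzma rose by 5.04 ± 0.76 (0.00253), Mki67, a marker of dividing cells, by 3.27 ± 0.60 (0.0145), and Fkbp5, a glucocorticoid target, by 2.99 ± 0.62 (at least 2.80, 0.0352), for which 0 of 2 probe sets passed when every probe set was tested (0.40 to 2.99). The cytokines Tnf (0.88 ± 0.89, adjusted p = 0.869) and Il1b (1.38 ± 0.68, adjusted p = 0.612) were not past the threshold. In total 44 genes rose and 0 fell. Of 54 splits of the labels, 1, the real one, reached that count, and the highest other gave 43. Splits did not exclude chance for the neutrophil list, whose median of 2.78 was reached in 3 of 54, the real one included. Of 21 neutrophil genes, 7 rose, 0 fell and 14 were not past (17 rose adjusted over the list alone; camera adjusted p = 2.06e-27, adjusted p = 0.0368 with an estimated correlation). Of 38 interferon response genes, 8 rose and 30 were not past (24 adjusted over the list alone; 2.94e-26, adjusted p = 0.0142 with an estimated correlation). Proliferation genes rose in 4 of 31, with 27 not past (20 adjusted over the list alone; 3.17e-19, adjusted p = 0.0587 with an estimated correlation), and NK cell and cytotoxic genes in 2 of 13, with 11 not past (7 adjusted over the list alone; 1.7e-07, adjusted p = 0.0889 with an estimated correlation). The neutrophil list averaged 6.31, 11.07 and 10.31 on platelet arrays at 0, 24 and 48 h, 6.40, 7.24 and 6.38 on Th1 arrays, and 5.24, 9.31 and 6.81 on Th2 arrays, where the 24 h arrays were at 10.70 and 7.93. The count was 105 and 761 without platelets 0 h replicates 1 and 2, 24 without either platelets 24 h replicate 1 or replicate 2, 27 without Th1 0 h replicate 2, 21 without Th2 24 h replicate 1 and 11 with a spread that did not depend on intensity.

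**Figure D3:**
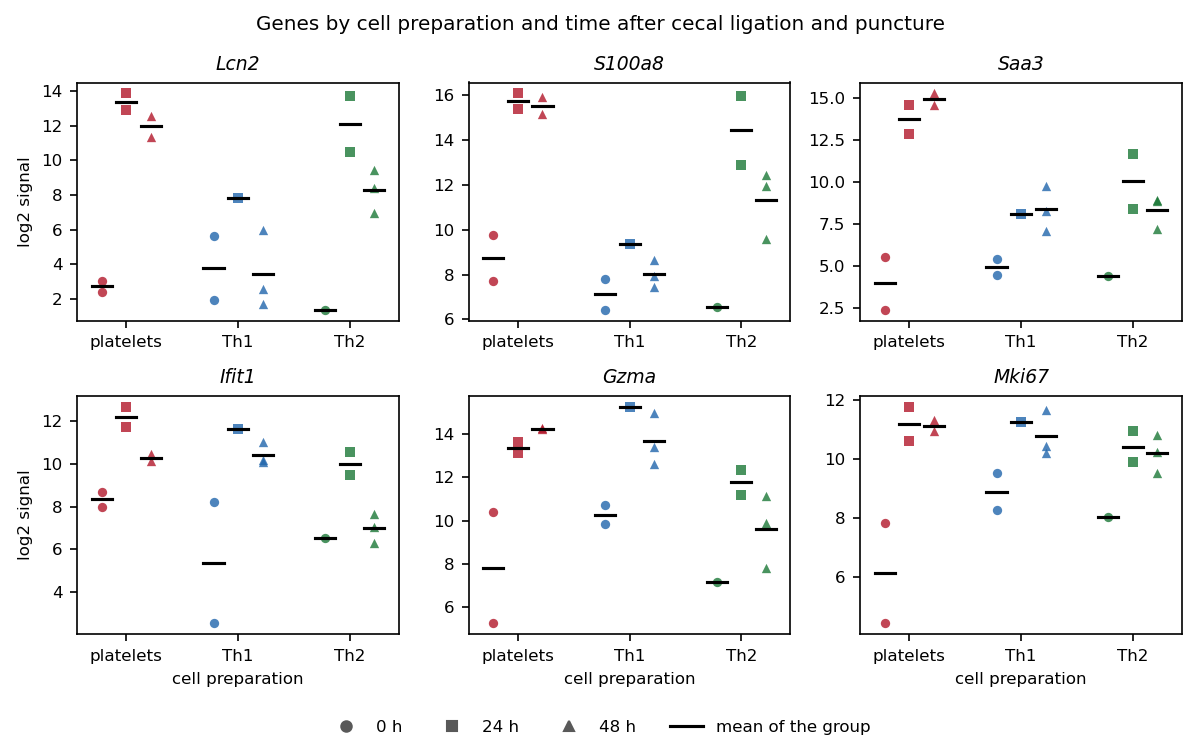
Log2 signal of Lcn2, S100a8, Saa3, Ifit1, Gzma and Mki67 by cell preparation, with a point per array, marker shapes for 0, 24 and 48 h and lines for group means. Lcn2 averaged 2.73, 13.38 and 11.97 on platelet arrays at 0, 24 and 48 h, 3.80, 7.83 and 3.42 on Th1 arrays, and 1.37, 12.08 and 8.27 on Th2 arrays.

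At 48 h against 0 h, averaged over the 3 cell types, some genes of cell division, inflammation and the glucocorticoid response rose, in numbers that depended on the model. Saa3 rose by 6.13 ± 0.68 (at least 4.57, log2, SE; 8 against 5 arrays; adjusted p = 0.000145), and Ncapg, which condenses chromosomes in mitosis, by 4.81 ± 0.79 (at least 1.09, 0.00577). Stfa2l1, a protease inhibitor, rose by 4.35 ± 0.95 (at least 2.29, 0.0425), and Rpn2, of protein glycosylation, by 4.23 ± 0.65 (at least 1.77, 0.00346). Nfkbia, the feedback inhibitor of NF-kB, rose by 2.54 ± 0.33 (0.000943), Cxcl2, a chemokine that draws neutrophils, by 4.02 ± 0.61 (at least 3.79, 0.00346), and Gzma by 4.08 ± 0.68 (0.00677). Ighm, the IgM heavy chain, rose by 3.15 ± 0.50 (0.00405). The cell types entered these averages unequally: on platelet, Th1 and Th2 arrays Nfkbia differed by 6.44 ± 0.55 (1.43e-06), 0.74 ± 0.50 (0.902) and 0.45 ± 0.64 (1), and Cxcl2 by 9.47 ± 1.03 (2.15e-05), -0.28 ± 0.94 (0.99) and 2.87 ± 1.19 (1). The NF-kB list averaged 6.01 at 0 h and 9.58 at 48 h on platelet arrays, 7.97 and 8.03 on Th1 arrays, and 7.74 and 8.33 on Th2 arrays. The glucocorticoid list averaged 6.60 and 9.33, 7.95 and 8.20, and 8.09 and 8.76 on the same arrays, and the proliferation list 5.78 and 8.78, 6.91 and 8.59, and 6.47 and 7.57. Gchfr, a regulator of cofactor synthesis for nitric oxide, fell by 2.91 ± 0.57 (by at least 2.70, 0.0217). Eif4ebp1, a repressor of translation, changed by -2.44 ± 0.48 (0.0221), and Sh3bgrl3 by -1.74 ± 0.38 (0.0409). Of the probe sets of Ighm, 1 of 10 passed (-0.46 to 3.15), of Nfkbia 2 of 5 (0.29 to 2.54), of Eif4ebp1 1 of 3 (-2.44 to 0.08) and of Ncapg 1 of 2 (0.58 to 4.81). The threshold was passed by 71 genes, of which 67 rose and 4 fell; 15 passed with the control level as a covariate, a setting chosen after seeing the data, and 5 with a spread that did not depend on intensity. Random splits of the labels did not exclude chance for the count of 71, which 5 of 100 splits reached, the real one included. The median change of all genes was 0.139, against -0.099 in the values as deposited. Of 31 proliferation genes, 5 rose and 26 were not past (18 adjusted over the list alone; camera adjusted p = 3.27e-18, adjusted p = 0.0587 with an estimated correlation). Of 28 NF-kB and inflammatory cytokine genes, 4 rose and 24 were not past (10 adjusted over the list alone; 3.36e-10, adjusted p = 0.0836 with an estimated correlation), and of 21 glucocorticoid response genes 4 rose and 17 were not past (7 adjusted over the list alone; 9.94e-07, adjusted p = 0.0889 with an estimated correlation). Neutrophil genes rose in 4 of 21, with 17 not past (10 adjusted over the list alone; 4.87e-10, adjusted p = 0.132 with an estimated correlation). The count was 216 and 1497 without platelets 0 h replicates 1 and 2, 20 and 22 without platelets 48 h replicates 1 and 4, 124 and 27 without Th1 0 h replicates 1 and 2, 33, 31 and 32 without Th1 48 h replicates 1, 2 and 4, and 40, 109 and 41 without Th2 48 h replicates 1, 2 and 4.

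Between 24 and 48 h the interferon genes were lower as a group, while no single gene passed. Of 38 interferon response genes, 0 passed over all genes and 7 fell adjusted over the list alone, with a median change of -0.90 (camera adjusted p = 6.22e-18, adjusted p = 0.0204 with an estimated correlation). The 21 neutrophil genes had a median of -1.51, and 8 fell adjusted over the list alone (1.19e-14, adjusted p = 0.0889 with an estimated correlation). Lcn2 differed by -3.21 ± 0.82 (log2, SE; 8 against 5 arrays; 0.999) and S100a8 by -1.55 ± 0.57 (0.999). MHC class II genes, which display antigen, had a median of 0.80 over 10 genes with none past (3.72e-05, adjusted p = 0.119 with an estimated correlation). With limma 0 genes passed, 639 had an unadjusted p under 0.05, and array weights gave 3.

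On platelet arrays alone, some NF-kB and inflammatory cytokine, neutrophil and interferon genes rose by 24 h. Lcn2 rose by 10.65 ± 1.39 (at least 7.40, log2, SE; 2 against 2 arrays; adjusted p = 0.000186), Saa3 by 9.79 ± 1.15 (at least 7.76, 9.16e-05), and Wfdc17, a protein of activated myeloid cells, by 8.05 ± 0.99 (at least 5.87, 0.000113). Nfkbia rose by 5.27 ± 0.55 (5.59e-05), Cxcl2 by 7.98 ± 1.03 (at least 7.28, 0.00018), and Psmb9, an immunoproteasome subunit, by 6.30 ± 0.76 (at least 3.93, 0.000101). S100a9 rose by 8.28 ± 1.41 (0.00198) and Chil3 by 8.13 ± 1.41 (at least 5.82, 0.00234). The largest falls, to dim signals, were those of Npat (-6.85 ± 1.29, at most -1.86), Zfp931 (-6.01 ± 1.44, at most -0.51), Agpat1 (at most -3.60), Zkscan7 (-5.87 ± 1.42, at most -1.34) and Smtnl2 (-5.83 ± 1.15, at most -2.48). Treml1, a receptor of platelet alpha granules, fell by 2.90 ± 0.68 (0.0199), and Itgb3, the partner of Itga2b, by a change of -2.12 ± 0.56 (0.0356), for which 0 of 2 probe sets passed when every probe set was tested (-2.12 to -0.76). For Nfkbia 4 of 5 passed (2.03 to 6.07), and for Npat (-6.85 to -1.30) and Agpat1 1 of 2. Pf4 (-0.54 ± 0.78, adjusted p = 0.775) was not past the threshold. The threshold was passed by 597 genes, of which 465 rose and 132 fell, and by 308 in the values as deposited, of which 280 rose and 28 fell. The median change of all genes was 0.145, against 0.264 in the values as deposited. Of 28 NF-kB and inflammatory cytokine genes, 11 rose and 17 were not past (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.98e-08, adjusted p = 0.113 with an estimated correlation). Of 21 neutrophil genes, 12 rose and 9 were not past (17 adjusted over the list alone; 8.09e-16, adjusted p = 0.0836 with an estimated correlation). Of 38 interferon response genes, 12 rose and 26 were not past (17 adjusted over the list alone; 6.82e-10, adjusted p = 0.0587 with an estimated correlation). Platelet and megakaryocyte genes fell in 3 of 31, with 28 not past (7 adjusted over the list alone; 7.48e-08, adjusted p = 0.333 with an estimated correlation). The count was 2438 without platelets 0 h replicate 2, 163 without platelets 24 h replicate 1 and 272 without platelets 24 h replicate 2. It was 9 in a fit of platelet arrays alone, 81 with array weights and 165 with a spread that did not depend on intensity.

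By 48 h the platelet arrays had gained some neutrophil, monocyte, NF-kB, chaperone and cell division transcripts. The median log2 change was 3.36 for the neutrophil list and 2.33 for the monocyte and macrophage list. Saa3 rose by 11.01 ± 1.15 (at least 8.98, log2, SE; 2 against 2 arrays; adjusted p = 1.96e-05), Cxcl2 by 9.47 ± 1.03 (at least 8.77, 2.15e-05), and Ctsc, the protease that activates granule enzymes, by 9.13 ± 1.01 (at least 8.39, 2.15e-05). Ptprc, the surface phosphatase CD45 of white cells, rose by 8.36 ± 1.29 (at least 7.98, 0.000588), Nfkbia by 6.44 ± 0.55 (1.43e-06) and Lcn2 by 9.24 ± 1.39 (at least 5.99, 0.000466). Of the probe sets of Ctsc, 1 of 3 passed (0.75 to 9.13), of Ptprc 1 of 2 (0.40 to 8.36) and of Nfkbia 3 of 5 (2.24 to 6.60). The largest falls, to dim signals, were those of Smr3a (-6.31 ± 1.48, at most -2.37), Rp1l1 (-5.95 ± 1.60, at most -1.85), Hmcn1 (-5.90 ± 1.70, at most -2.74), Brdt (-5.85 ± 1.53, at most -2.44, 1 of 3 probe sets past) and Meioc (-5.72 ± 1.45, at most -0.72). Ctss, a protease of antigen-presenting cells, rose by 7.73 ± 0.89 (3.76e-05), Mpeg1, a pore protein of macrophages, by 5.91 ± 0.80 (0.000155), and Casp1, the inflammasome protease, by 5.39 ± 1.17 (at least 3.44, 0.00747). Treml1 fell by 2.34 ± 0.68 (0.0443), and Selp, the adhesion receptor of activated platelets, was not past (1.61 ± 1.27, adjusted p = 0.513). In all, 1064 genes passed, 940 up and 124 down. The median change of all genes was 0.29, against -0.155 in the values as deposited. Of 28 NF-kB and inflammatory cytokine genes, 15 rose and 13 were not past (18 adjusted over the list alone; camera adjusted p = 1.61e-12, adjusted p = 0.0587 with an estimated correlation). Of 21 monocyte and macrophage genes, 7 rose and 14 were not past (7 adjusted over the list alone; 1.26e-05, adjusted p = 0.171 with an estimated correlation). Heat shock and chaperone genes rose in 6 of 15, with 9 not past (10 adjusted over the list alone; 2.11e-05, adjusted p = 0.193 with an estimated correlation), and proliferation genes in 12 of 31, with 19 not past (19 adjusted over the list alone; 4.87e-10, adjusted p = 0.124 with an estimated correlation). The count was 3170 without platelets 0 h replicate 2, 240 without platelets 48 h replicate 1, 177 without platelets 48 h replicate 4, 21 in a fit of platelet arrays alone and 407 with a spread that did not depend on intensity. The control levels of the 48 h arrays were 11.27 and 12.68, and the count was 348 with the control level as a covariate, a setting chosen after seeing the data.

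On the 1 Th1 array at 24 h, interferon genes were higher as a group, with a spread pooled over the groups. Of 38 interferon response genes, 0 passed over all genes, 2 rose adjusted over the list alone, and the median change was 1.71 (1 against 2 arrays; camera adjusted p = 1.26e-11, adjusted p = 0.0493 with an estimated correlation). Fkbp5 differed by 3.82 ± 1.13 (log2, SE) and Gzma by 4.98 ± 1.40, neither past the threshold. The 31 proliferation genes had a median of 2.22 at 24 h (4.8e-10, adjusted p = 0.124 with an estimated correlation) and of 1.72 at 48 h (4.87e-10, adjusted p = 0.124 with an estimated correlation), with none past over all genes. Tbx21 differed by 0.00 ± 1.08 at 24 h and by -0.21 ± 0.81 (limma adjusted p = 0.991) at 48 h. Ifng differed by 1.79 ± 1.89 and 1.78 ± 1.41 (0.924), and neither gene passed at either time. The median change of all genes was 0.123 at 24 h, against -0.258 in the values as deposited, and 0.081 at 48 h, against -0.16. With limma 0 genes passed at 24 h, with 682 at an unadjusted p under 0.05, and 4 without Th1 0 h replicate 1. At 48 h 0 genes passed, with 1068 at an unadjusted p under 0.05, 4 with array weights, 17 in a fit of Th1 arrays alone, and 18 without Th1 0 h replicate 1.

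On Th2 arrays, 4 neutrophil and myeloid genes passed the threshold at 24 h against the 1 array at 0 h, with a spread pooled over the groups. Lcn2 was higher by 10.72 ± 1.70 (at least 6.11, log2, SE; 2 against 1 arrays; adjusted p = 0.0149), Slfn4 by 10.29 ± 1.37 (at least 7.26, 0.00322), S100a9 by 10.05 ± 1.72 (at least 6.58, 0.0323), and S100a8 by 7.86 ± 1.17 (0.00863). Of 21 neutrophil genes, 3 were higher and 18 not past (11 adjusted over the list alone; camera adjusted p = 1.22e-28, adjusted p = 0.0368 with an estimated correlation). The 38 interferon response genes had a median change of 1.30, with 0 past over all genes and 1 adjusted over the list alone (2.99e-13, adjusted p = 0.0375 with an estimated correlation). Gata3 and Il4 were not past the threshold (adjusted p = 1 each), and their means at both times lay under the median of all probe sets. The count of 4 was 0 with a spread that did not depend on intensity, 13 without either platelets 0 h replicate 1 or replicate 2, 2 without either platelets 24 h array, and 0 and 7 without Th2 24 h replicates 1 and 2. At 48 h against 0 h, Lcn2 differed by 6.90 ± 1.60 and S100a8 by 4.76 ± 1.10 (3 against 1 arrays), neither past the threshold. The median change of all genes was -0.12 at 24 h and -0.114 at 48 h, against -0.081 and -0.151 in the values as deposited. At 48 h limma called 0 genes, 417 had an unadjusted p under 0.05, array weights gave 14, and the count was 3 without either platelets 0 h array and 1 without either Th2 24 h array.

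The 48 h response of platelets exceeded that of T cells for some inflammatory and myeloid genes in a direct test of the difference. Ccl9 and Ccl6, chemokines of myeloid cells, differed by 9.73 ± 1.68 (log2, SE; adjusted p = 0.00585) and 9.10 ± 1.12 (0.000216), Nfkbia by 5.84 ± 0.69 (0.000216), and Ctss by 7.90 ± 1.10 (0.000795). Il1b, the inflammasome cytokine, differed by 5.14 ± 1.27 (0.048). Fabp7 (9.56 ± 2.16), Smpdl3a (9.17 ± 1.70) and Pla2g7 (8.56 ± 1.95) also differed. Their platelet means at 0 h, 2.57, 3.11 and 3.45, lay under the median of all probe sets, as did that of Ccl9 (5.12). Ndp (-8.47 ± 1.70), G6pc3 (-6.80 ± 1.52), Edn3 (-6.28 ± 1.42), Phgr1 (-5.96 ± 1.36) and Slc6a4 (-5.60 ± 1.04) differed the other way. Their signals on the lone Th2 0 h array were 1.07, 2.39, 3.68, 1.93 and 1.84, under that median. Of the probe sets of Ccl9, 1 of 2 passed (2.33 to 9.73), of Ccl6 1 of 2 (6.51 to 9.10), of Nfkbia 3 of 5 (2.92 to 6.25) and of Edn3 1 of 4 (-6.28 to 1.69). For 195 genes the difference was positive and for 12 negative, 207 in all. The median difference of all genes was 0.302, against 0.063 in the values as deposited. Of 28 NF-kB and inflammatory cytokine genes, 9 were past with a larger rise in platelets and 19 were not past (15 adjusted over the list alone; camera adjusted p = 2.58e-11, adjusted p = 0.0772 with an estimated correlation). Of 21 monocyte and macrophage genes, 3 had a larger rise in platelets and 18 were not past (8 adjusted over the list alone; 1.12e-05, adjusted p = 0.17 with an estimated correlation). The count was 2058 without platelets 0 h replicate 2, 22 and 27 without platelets 48 h replicates 1 and 4, 74 and 125 without Th1 0 h replicates 1 and 2, 116, 118 and 119 without Th1 48 h replicates 1, 2 and 4, 130 without Th2 48 h replicate 4, and 2 with a spread that did not depend on intensity.

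Th1 and Th2 responses were compared in the same way. At 48 h the neutrophil genes had a median difference, Th1 minus Th2, of -1.64, with 0 of 21 past over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000136, adjusted p = 0.332 with an estimated correlation). The median difference of all genes was 0.187, and 0.273 at 24 h, against 0.05 and -0.108 in the values as deposited. S100a8 differed at 48 h by -3.85 ± 1.41 (log2, SE; adjusted p = 1). At 24 h, a comparison chosen after seeing the data, the median of the neutrophil genes was -2.45, with 3 of 21 past adjusted over the list alone (1.94e-11, adjusted p = 0.101 with an estimated correlation). With limma 0 genes passed at either time, with 520 at an unadjusted p under 0.05 at 48 h and 498 at 24 h, and 0 under every alternative setting run.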

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

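Of the tests in this part, those of platelets carried into the Th1 preparation, of exchanged labels, of neutrophils carried in, of a single 0 h array, of a lower share of platelets, of the size of the platelet changes with the covariate and of the neutrophil list over other splits were chosen only after the result was seen, as was the setting with the control level as a covariate.

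An array and a comparison stood out. On platelets 48 h replicate 1 the Gapdh 3' minus 5' difference was 4.405, far from the nearest of the 6 platelet arrays at 3.01, in 1 of 12 such tests, of which chance picks out about 1 in 20. A larger 3' excess goes with more degraded or more shortened amplified RNA, and its cause was not tested. The 48 h response differed between platelets and T cells for 207 genes in the direct test of the difference, which rests on 2 platelet arrays at each time.

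Platelet transcripts were abundant on the arrays labelled Th1. An exchange of labels with platelet arrays was excluded by the T cell list, which lay higher on Th1 than on platelet arrays by 2.219 on the log2 scale. The array yield was excluded as the whole cause, since the median difference of the platelet list from Th2 was 5.274 with the control level as a covariate against 5.306 without it. A chance split of these arrays could be excluded, with 674 genes in the real split and at most 13 in another of the 100 splits drawn. Since the replicates may be technical, such splits do not exclude a chance difference between pools. Of 25 abundant platelet genes, 25 (100%) were higher on Th1 than on Th2 arrays by over 1. This share repeats the pattern. It cannot tell platelets carried into the preparation, or bound to the cells, from a true difference of the cells. The platelet list averaged 12.22 ± 0.38 on Th1 arrays and 10.92 ± 0.95 on platelet arrays. The T cell list averaged 8.43 on Th1 and 8.42 on Th2 arrays.

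Neutrophil transcripts were higher after 24 h. The array yield was excluded as the whole cause, since the median change of the list was 2.606 with the control level as a covariate against 2.780 without it. Chance could not be excluded for the neutrophil list, whose median of 2.780 was reached in 3 of 54 splits, the real one included, and was 3.158 in another; for the count of all genes it could be excluded by 1 gene only, 44 in the real split against at most 43, a count that ran from 21 to 761 with an array left out. The share of neutrophil genes that rose cannot tell neutrophils carried into the preparations from induction within the isolated cells. Of all 21 measured neutrophil genes, 19 (90.5%) were higher by over 1, and 11 of the 11 abundant at 24 h, which either would give. Whether the transcripts on platelet arrays arose within the platelets was not tested. Lcn2 reached a log2 signal of 13.38 on platelet and 12.08 on Th2 arrays at 24 h. Negative selection should remove neutrophils, but transcripts of other blood cells were present after it. The B cell list, for example, averaged 10.68 on Th2 arrays against 7.36 on Th1 arrays, so the selection decides nothing here.

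Platelet arrays changed broadly by 48 h. The explanation tested was a lower share of platelets with an unchanged mix of the other cells. The lists of other cells did not move alike on these arrays, which argues against it. Their medians were 3.359 for neutrophil, 2.332 for monocyte, 1.333 for T cell, 1.244 for erythroid and 0.03 for B cell genes. The gap between neutrophil and B cell genes was 3.329. It was judged against the spread between the genes of a list. The spread between arrays, 2 at each time, did not enter it, and the platelet arrays at 0 h correlated at 0.323. An earlier version of the test, which asked for a list median below 0, decided nothing. A lower share of platelets with a changed mix of other cells was not tested. Array yield and time cannot be told apart, since the control level moved with time: with it as a covariate 348 genes passed, while the median change of the 1064 went only from 4.07 to 3.35 and its median SE from 0.95 to 1.06, so that smaller changes and larger errors both ended calls (a first version, set before the result was seen, used the count alone). The 0 h array of replicate 1 could explain a part too: without it 731 genes passed, 495 of the 1064 among them, whereas the same loss of replicate 2 left 3170, 975 of the 1064 among them (earlier versions of this test used the 731 alone, or no such loss for comparison). A yield effect, other blood cells carried into the platelet preparations in a changed mix, and a response of the cells to the operation all stay open.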

How the results depend on the processing

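Named genes numbered 363 over the comparisons, 296 past the threshold. Of the 296, 141 stayed past under every setting that used the representative probe set of each gene, and 0 reversed. A further 13 became newly past under some such setting. The setting of every probe set did not enter these counts. Counts in the next 2 paragraphs moved by over 1.5 times; unless said otherwise, the cause was not tested. The settings without 4 arrays and with the covariate were chosen after seeing the data, as were the comparisons of platelets with Th1 and Th2.

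With every probe set, which tests more features, platelets against T cells gave 2076 (1337 in the report), Th1 against Th2 1068 (674), platelets against Th1 449 (291) and platelets against Th2 3070 (1913). With values as deposited, 48 h against 0 h gave 107 (71), platelets at 24 h 308 (597, with 90.9% against 77.9% higher), Th2 at 48 h 1 (0) and platelets against Th1 437. Array weights gave 1229 for Th1 against Th2, 72 for 24 h against 0 h (44), 329 for 48 h against 0 h, 3 for 48 h against 24 h (0), 81 and 491 for platelets at 24 and 48 h (1064), 4 for Th1 at 48 h (0), 14 for Th2 at 24 h (4), 14 for Th2 at 48 h and 441 for platelets against Th1. Without an intensity trend the counts were 812 for platelets against T cells, 11 for 24 h against 0 h, 5 for 48 h against 0 h, 165 and 407 for platelets at 24 and 48 h, 0 for Th2 at 24 h, 2 for the 48 h response of platelets minus T cells (207) and 93 for platelets against Th1.

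Without the 4 arrays of highest control signal (Th2 24 h replicate 1, platelets 0 h replicate 1, Th1 0 h replicate 2 and Th2 48 h replicate 2), they were 2351 for platelets against T cells, 90 for 24 h against 0 h, 265 for 48 h against 0 h, 1137 for platelets at 24 h, 3 for Th1 at 48 h, 2 for Th2 at 24 h, 6 for Th2 at 48 h, 398 for platelets minus T cells at 48 h, 773 for platelets against Th1 and 3055 for platelets against Th2. With the control level as a covariate, they were 15 for 48 h against 0 h and 905 and 348 for platelets at 24 and 48 h. In fits of 1 cell type, with fewer arrays to estimate the spread, platelets at 24 and 48 h gave 9 and 21 and Th1 at 48 h 17.

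The replicate numbers showed no clear pairing of the arrays. Deviations of same-numbered arrays had a median correlation of -0.009 over 39 pairs (-0.19 to 0.164, 2 over 0.1). Within a time it was 0.024 over 11 pairs (2 over 0.1), against -0.02 over 18 pairs of other number (0 over 0.1). Of 16 arrays, 9 correlated best with their own number, so a weak pairing is not excluded. With the number as a block, 48 h against 0 h gave 13, platelets at 48 h 498, Th2 at 24 h 2 and platelets minus T cells at 48 h 100. A block within time, possible for the cell comparisons, gave 1494, 560, 318 and 1848 for platelets against T cells, Th1 against Th2, platelets against Th1 and platelets against Th2.

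Leaving out each array in turn gave 688 to 2968 for platelets against T cells, 535 to 1184 for Th1 against Th2, 21 to 761 for 24 h and 20 to 1497 for 48 h against 0 h, 0 to 0 for 48 h against 24 h, 163 to 2438 and 177 to 3170 for platelets at 24 and 48 h, 0 to 4 and 0 to 18 for Th1, 0 to 13 and 0 to 3 for Th2, 22 to 2058 for platelets minus T cells at 48 h, 0 to 0 for Th1 minus Th2 at 48 and at 24 h, 125 to 2109 for platelets against Th1 and 1248 to 3133 for platelets against Th2.

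Of 403 list tests, 141 were called; 12 of these kept their call with an estimated correlation and 66 with fry, which called 67. Leaving out arrays gave 57 to 159, with 91 without Th1 24 h replicate 1 and 57 without Th2 0 h replicate 1, where comparisons drop out by construction. Signal limits the dimmer genes: the median probe set was at 5.97, the 90th percentile at 8.64 and the highest at 16.43.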

Other observations

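The comparisons of platelets with Th1 and with Th2 arrays tested in this part were chosen only after the data were seen.

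On platelet arrays at 48 h, 13 of 78 receptor genes rose and 65 were not past (13 adjusted over the list alone; camera adjusted p = 0.000438, adjusted p = 0.179 with an estimated correlation). Csf2rb, the shared receptor chain of interleukin 3 and GM-CSF, rose there by 6.88 ± 1.10 (at least 5.92, log2, SE, 2 against 2 arrays; limma adjusted p = 0.000895), and Icam1, an adhesion ligand of leukocyte integrins, by 5.08 ± 0.82 (at least 3.70, 0.000926). For Csf2rb 1 of 2 probe sets passed (1.83 to 6.88). Between Th1 and Th2 arrays, P2ry12, the ADP receptor of platelets, differed by 5.43 ± 0.71 (at least 5.26, 1.77e-05), Selp by 3.84 ± 0.81 (at least 3.10, 0.00471) and Cd40, the receptor for the Cd40lg signal of T cells and platelets, by -5.34 ± 0.63 (4.66e-06), while Cd40lg itself was not past (1.76 ± 0.74, adjusted p = 0.281).

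Labels were regrouped at random for the other comparisons of at least 3 arrays a side. These splits too leave a chance difference between pools open, as the replicates may be technical. For platelets against T cells chance could be excluded, with 1337 genes in the real split and at most 318 in another of 100 splits, 1 of which, the real one, gave as many. It could be excluded for platelets against Th1, with 291 genes against at most 141, and for platelets against Th2, with 1913 against at most 1312. Chance could not be excluded for 48 h against 0 h, where the real split gave 71 genes, 5 of 100 splits gave as many and another gave 891, several times the real count, which points to a structure of the samples that was not identified. For 48 h against 24 h the real split gave 0 genes, which all 100 splits reach by construction, so the splits decide nothing there; the highest other gave 141.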
